A study of Homo sapiens with 6 samples.

How the data were processed

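Genome-wide CRISPR knockout was measured as guide DNA reads in HEK293 cells carrying the P-In or the E-In reporter. Per the labels, cells were selected with puromycin for 7 days, 4000000 cells were collected as the unsorted control and 40000000 were sorted for the high-GFP pool; the number of cells recovered in each sorted pool is not given in the sources used here. The control corresponds to 51.7 cells per guide. The authors deposited counts, raw reads per guide without normalization, for 6 libraries in 1 table; they name Bowtie and MAGeCK without a version or a role. Guide DNA was amplified by PCR before sequencing, so reads are not independent molecules.

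Libraries were grouped by reporter and pool as the labels give them, with 1 library per group and no replicates. Total reads ranged from 31193027 to 38743299. The sequences of all 77441 guides were distinct. Gene names that a spreadsheet had turned into dates numbered 26, and 2 of these held 8 guides from more than 1 gene and were left out of the gene tests. Guides were searched in the hg38 primary chromosomes for perfect matches next to an NGG motif and placed in GENCODE protein-coding features. Of 76441 targeting guides 73354 had 1 site and 3087 had 2 or more; 0 non-targeting guides had a site.

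For each reporter 3 comparisons were made: high-GFP against low-GFP, and each sorted pool against the input, which those last comparisons share. Counts of the libraries compared were scaled by the median of ratios, a pseudocount of 5 was added, and log2 ratios were taken for guides with at least 10 reads in either library. Genes with at least 3 such guides were tested by robust rank aggregation, the gene test that MAGeCK uses, written here in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The aggregation used the top 25% of ranks, one-sided in each direction. P-values came from 1000000 random guide sets per number of guides, the smallest possible being 1e-06, with Benjamini-Hochberg adjustment at 0.05. This permutation test compares guides within a pair of libraries and holds no error between sorts. A fold of reads against an absent gene used a floor of 3 counts over its guides.

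The reporters were compared by the overlap of the top 1% of genes with a hypergeometric exact test and by Fisher's method on the gene p-values. A joint fit of gene sums over all 6 libraries used edgeR 4.0.16 (R 4.3.3) with TMM, filterByExpr and quasi-likelihood tests, with the reporter as an additive term. The fitted common dispersion was 0.0698. The median log2 ratios of gene lists fixed in advance were placed among 10000 random lists of the same size matched on mean reads in 20 bins, as a description and not a test. The microRNA list, with 2 genes in the table, was too small for this.

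Named genes were chosen by a rule fixed before the data were examined: the 10 smallest p-values per reporter and direction, up to 10 genes per direction in the top 1% of both reporters, the 3 smallest combined p-values, up to 4 passing members per list, the 3 smallest p-values per direction against input, and all SR protein genes. Other genes that passed over their list alone, such as LEO1, METTL3, METTL14, PTBP1, SMG9 and TTC37, and the shared top 1% genes beyond that rule were named after their values were seen.

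Simulated counts, in which 200 genes were changed, had the observed mean reads and 1 dispersion per reporter, without loss of guides in the sorts. The rank test was tested on them. With the E-In spread (dispersion 0.118) it found 10 of 67 genes changed 2-fold, 59 of 67 changed 4-fold and 66 of 66 changed 8-fold, with 3 false calls. With the P-In spread (dispersion 0.527) it found 0, 0 and 4, with 0 false calls. With gene names shuffled among guides it called 0 genes in each reporter. The shuffle repeats the random ranks that the test itself assumes. It therefore checks the calculation and not errors from guides with few reads or several sites. The edgeR fit found 94 of 100 genes changed 4-fold and 100 of 100 changed 8-fold, with 13 false calls. Its simulated counts gave all 6 libraries the same mean shares and 1 dispersion (0.0698). The wider spread in P-In was therefore not modelled there.

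Alternatives fixed in advance were scaling by total reads or on non-targeting guides, pseudocounts of 1 and 20, no filter, at least 50 reads or a filter on the input, the top 10% of ranks or all ranks, a negative binomial score, leaving out the most extreme guide of each gene, a threshold of 0.25, the top 5% overlap, the squared larger p-value, and in edgeR no TMM, no filter, the sorted libraries alone, DESeq2 1.42.0 and fry on guides (limma 3.58.1). Figures were drawn with matplotlib 3.10.9.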

Results

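The screen covered 6 guide libraries from HEK293 cells, a human embryonic kidney line, that carried a genome-wide CRISPR knockout library. The cells held 1 of 2 green fluorescent protein (GFP) reporters, called P-In and E-In, for exon-intron circular RNAs, which are circular transcripts that keep an intron between their exons. For each reporter there was an unsorted input library, a library from cells sorted for high GFP and a library from cells sorted for low GFP. Each group had 1 library, so no spread between repeated sorts was available for either reporter. The screen asked which genes, when cut, move cells toward higher or lower reporter fluorescence. A guide that is more frequent in the high-GFP pool marks a gene whose loss went with more fluorescence.

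The table gave raw read counts for 77441 guides, of which 76441 were aimed at 19112 gene names and 1000 were non-targeting. The P-In libraries held 32032215 reads in the input, 33052981 in high-GFP and 33136036 in low-GFP. The E-In libraries held 31193027, 38743299 and 36859852 reads in the same order. In the P-In sorted pools 6.99% of guides had 0 reads in high-GFP (95% Wilson interval 6.81 to 7.17) and 5.77% in low-GFP (5.61 to 5.94), against 1.60% in the input (1.51 to 1.69). In E-In these shares were 0.957% (0.891 to 1.03) in high-GFP, 0.677% (0.621 to 0.737) in low-GFP and 0.874% (0.811 to 0.942) in the input. Among guides with at least 100 input reads, 2708 had 0 reads in the P-In high-GFP pool and 2036 in the P-In low-GFP pool, against 151 and 93 in E-In.

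Guides against genes that dividing cells need were scarce in the unsorted cells. Proteasome guides had a median of 114.5 reads in the P-In input and 195.5 in the E-In input, and cytosolic ribosome guides had 134.5 and 161.5. Guides against DNA replication genes had medians of 180 and 241 reads. Guides against olfactory receptors, which HEK293 cells are not known to use, had medians of 362 and 358.5 reads. Non-targeting guides were more frequent than all of these, with medians of 897 and 843.5 reads.

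In E-In cells, the lists of SR proteins, U1 and Sm snRNP genes and cleavage and polyadenylation genes lay toward the high-GFP pool. So did those of DNA replication and proteasome genes. The lists of RNA polymerase II and elongation genes and of m6A genes lay toward the low-GFP pool. The comparison of high-GFP with low-GFP passed 75 of 19099 genes at a false discovery rate of 0.05, 53 of them higher in high-GFP and 22 higher in low-GFP. The largest median log2 ratio among the named genes was that of HEXIM1, an inhibitor of the elongation kinase P-TEFb, at 4.02 ± 1.76 (SD over 4 guides). DHX9, an RNA helicase that unwinds paired repeats in introns, had 3.73 ± 2.36, and ZFC3H1, a factor of nuclear RNA decay, had 3.69 ± 1.29. EIF4E, which binds the messenger RNA cap, rose from 742 reads in low-GFP to 9732 in high-GFP, a 12.4-fold difference in scaled reads with a median log2 ratio of 3.48 ± 0.57.

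SRSF1, the SR protein that binds exonic splicing enhancers, had 1554 reads in the E-In high-GFP pool and 401 in low-GFP. Its median log2 ratio was 2.58 ± 1.27 (SD over 4 guides), with all 4 guides higher in high-GFP (one-sided permutation p = 1.6e-05, false discovery rate 0.0139). SRSF1 no longer passed when guides were ranked only against guides of similar read number (false discovery rate 0.0732), and neither did SRSF7, SRRT, PCNA, PSMA6, PSMB5 and DHX15. With single-site guides only, SRSF7, DHX15 and PSMA5 no longer passed. SRSF7 also passed, at 2.05 ± 1.54. Of the 15 SR protein genes tested, 13 had a median ratio above 0, and 5 passed when adjusted over the list alone: SRSF1, SRSF2, SRSF5, SRSF7 and TRA2A. Guides against SRSF6 went the other way, at -1.15 ± 1.58, without passing. The median of the SR list was 0.60, higher than in 100% of 10000 random lists matched on read number.

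Members of other RNA-processing lists went both ways in E-In. Toward high-GFP, LUC7L3, a U1 snRNP-associated protein, had a median log2 ratio of 3.19 ± 0.73, and HNRNPU, a nuclear matrix RNA-binding protein, 3.44 ± 0.98. The cleavage and polyadenylation list had a median of 0.42, and 7 of its 22 genes passed when adjusted over the list alone. Of these, PCF11 (2.63 ± 0.35) and PAPOLA (2.24 ± 0.34) also passed over all genes tested. SRRT, which links the cap-binding complex to RNA export and decay, had 3.34 ± 1.38, and SMG1, a kinase of nonsense-mediated decay, 2.75 ± 1.86. The medians were 0.48 for U1 and Sm snRNP genes, 0.55 for SR protein kinases and transport, 0.27 for hnRNP proteins, 0.38 for nonsense-mediated decay and 0.25 for the RNA exosome and exonucleases. Each of these 5 medians lay above the 99th percentile of its random lists. Adjusted over the list alone, 3 hnRNP genes passed toward high-GFP and 2, PTBP1 and PCBP2, toward low-GFP, with 16 of 29 medians above 0. For nonsense-mediated decay 4 genes passed toward high-GFP and 3, SMG9, ETF1 and GSPT1, toward low-GFP. For the exosome and exonucleases 6 passed toward high-GFP and 3, TTC37, WDR61 and CNOT2, toward low-GFP. RNA export had 4 and 3.

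The other spliceosome lists had medians nearer 0 or below it, and differences between lists were not tested. The median log2 ratios in E-In were 0.04 for U2 snRNP genes, 0.13 for the U4/U6.U5 tri-snRNP, 0.01 for the PRP19 complex and -0.18 for the minor spliceosome. They lay at the 62.9th, 87.0th, 54.0th and 12.8th percentiles of random lists. DHX15, a spliceosome disassembly helicase, was the 1 member of these lists past the threshold over all genes, at 1.86 ± 0.82. Adjusted over the list alone, SF3A2, SNRPB2 and SNRNP200 passed toward low-GFP and PDCD7, of the minor spliceosome, toward high-GFP.

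The DNA replication list had a median of 0.68 in E-In and the proteasome list 0.60, both toward high-GFP. Like the SR list, both lay above 100% of their random lists, so that rank was not particular to RNA-processing lists. The cytosolic ribosome list had -0.06, with 13 genes past the threshold toward high-GFP and 25 toward low-GFP when adjusted over the list alone. PCNA, the replication clamp, passed at 2.11 ± 4.75, where 3 of its 4 guides were higher. PSMB5, PSMA6 and PSMA5 passed for the proteasome, with PSMB5 at 2.30 ± 0.88. Translation initiation genes split, with EIF4E, EIF4G1, EIF3C and EIF3E higher in high-GFP and EIF3B higher in low-GFP (-2.62 ± 1.05). All 4 guides of EIF3C also matched a second site in the genome, as did 2 guides of EIF4E.

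On the low-GFP side of E-In, RELA, a subunit of the transcription factor NF-kB, had a median log2 ratio of -2.48 ± 0.33, and TNFRSF1A, a tumour necrosis factor receptor that signals to NF-kB, had -2.14 ± 0.73. YTHDC1, the nuclear reader of m6A, had -3.08 ± 0.63, and RBM15, a subunit of the m6A writer, -1.99 ± 1.82. METTL3 and METTL14, the writer's core, passed when adjusted over the list alone, and the median of the m6A list was -0.28, at the 0.58th percentile. PA2G4, a growth-regulated RNA-binding protein, had the lowest ratio of the named genes, -4.52 ± 2.06, with 312 reads in high-GFP and 9502 in low-GFP. CDK9, the kinase of P-TEFb, had -2.10 ± 1.40, and the elongation factors SUPT4H1 and SUPT5H had -2.89 ± 2.11 and -2.75 ± 1.23. With guides filtered on input reads, CDK9 no longer passed. The RNA polymerase II and elongation list had a median of -0.28, at the 0.02nd percentile. CDK12 (1.86 ± 0.54) and CDK13 (2.36 ± 1.01), which also phosphorylate the polymerase tail, were higher in high-GFP. CDK13 no longer passed with a pseudocount of 1 or with all ranks.

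Of the growth suppressors, NF2 passed over all genes at -2.47 ± 1.01, and TSC1 and TSC2 passed toward low-GFP and CUL3 toward high-GFP when adjusted over the list alone. The median of this list was -0.26, at the 0.3rd percentile. The mTOR and cell growth list had 0.26, at the 99.1st percentile, where MTOR and RPTOR passed toward high-GFP and TSC1 and TSC2 toward low-GFP over the list alone. MORC2, which silences inserted DNA, had -2.56 ± 1.94. The remaining lists had medians of -0.15 for transgene silencing, -0.13 for innate RNA sensing, -0.05 for reported regulators of circular RNAs, -0.01 for Mediator, 0.02 for RNA export, 0.05 for translation initiation and 0.08 for the exon junction complex. Scaling on the non-targeting guides moved the median of all genes to 0.15, so the medians of transgene silencing, innate RNA sensing, the ribosome, circular RNA regulators and Mediator changed sign under it. The 374 olfactory receptor genes had a median of 0.01, and 0 of them passed.

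**Figure D1:**
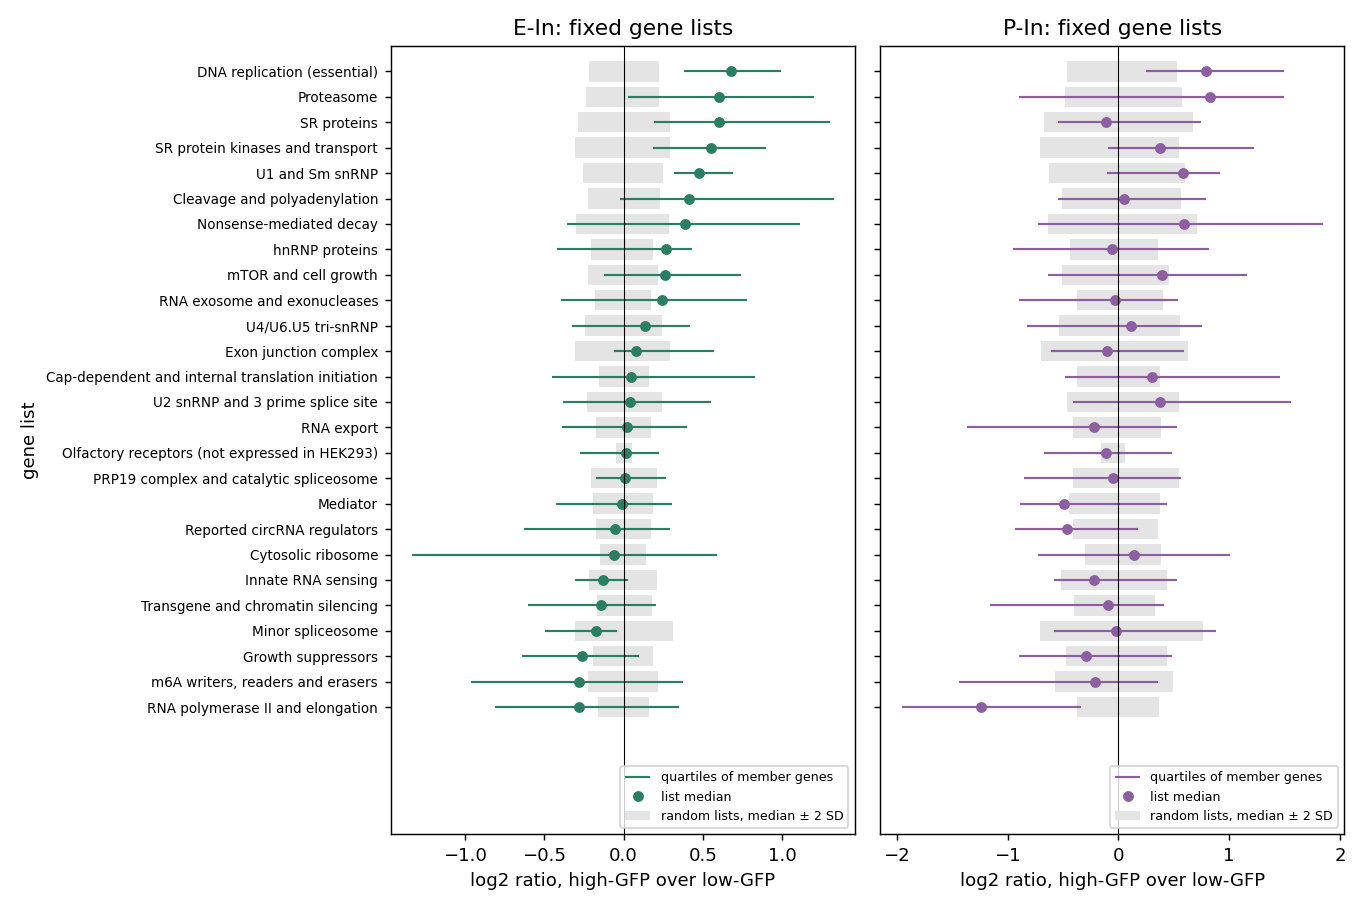
Median log2 ratio of guide reads in high-GFP over low-GFP for each fixed gene list (points), with quartiles of its member genes (lines) and 2 SD around the median of 10000 random lists matched on read number (grey bars), in E-In (left) and P-In (right). SR proteins lie at 0.60 in E-In and -0.11 in P-In, where the sign changed under 2 other scalings, and RNA polymerase II and elongation genes lie at -0.28 and -1.24.

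In P-In cells, loss of DHX9 went with high GFP and loss of the elongation factors SUPT4H1 and SUPT6H with low GFP. These were the 3 genes of 19011 that passed. DHX9 had 3264 reads in high-GFP and 55 in low-GFP, a 54.4-fold difference in scaled reads (median log2 ratio 6.96 ± 2.48, SD over 4 guides, one-sided permutation p = 1e-06, the smallest that the permutations can give). SUPT4H1 had 335 reads in high-GFP and 7436 in low-GFP, a 24.2-fold difference over 3 guides (permutation p = 1e-06). SUPT6H had 0 reads in high-GFP and 4300 in low-GFP (median log2 ratio -6.80). With the absent side set at 3 counts over the gene's guides, this is 1565-fold lower in high-GFP. That fold is no lower bound, since guides lost in the sort also give 0 reads. In E-In the median log2 ratio of SUPT6H was -1.68, without passing over all genes. Intervals and floors cover counting error only.

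The polymerase and elongation list had a median log2 ratio of -1.24 in P-In, lower than all random lists, and 7 of its 42 genes passed toward low-GFP when adjusted over the list alone. Those 7 included SUPT5H (-4.28 ± 2.93), PAF1 (-3.49 ± 0.79), LEO1 and CDC73, the last 3 being subunits of the PAF complex. CELF1, a GU-rich element binding protein, had -4.18 ± 0.57 without passing over all genes (permutation p = 5.9e-05, false discovery rate 0.374). Mediator had a median of -0.49 (1.29th percentile) and reported regulators of circular RNAs -0.46 (1.02nd percentile). The proteasome list had 0.82 and the DNA replication list 0.79, both at the 99.9th percentile. The median of the SR protein list was -0.11, at the 36.6th percentile, and it changed sign when libraries were scaled by total reads or on non-targeting guides. Cleavage and polyadenylation genes had 0.05 (53.9th percentile), m6A genes -0.21 (24.7th), hnRNP proteins -0.06 (46.6th) and the exosome and exonucleases -0.03 (40.3rd). Higher were U1 and Sm snRNP genes at 0.58 (97.2nd), nonsense-mediated decay at 0.60 (95.7th) and SR protein kinases and transport at 0.38 (92.3rd).

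SRSF1 had 716 reads in the P-In high-GFP pool and 161 in low-GFP (median log2 ratio 2.08 ± 2.32, permutation p = 0.0649, false discovery rate 0.856). The ratio rested on 3 guides, and 3 of the 4 SRSF1 guides had 0 reads in the P-In input. EIF4E had 2.12 ± 0.87 in P-In with all 4 guides higher in high-GFP, and SRSF7 had 3.77 ± 5.22 with 2 of 3 guides higher. Simulated counts with the P-In spread gave 4 of 66 genes past the threshold at an 8-fold change, against 66 of 66 with the E-In spread. The simulation used 1 dispersion per reporter and did not model the guides lost in the P-In sorts. These shares are therefore only a rough guide to what P-In could detect.

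**Figure D2:**
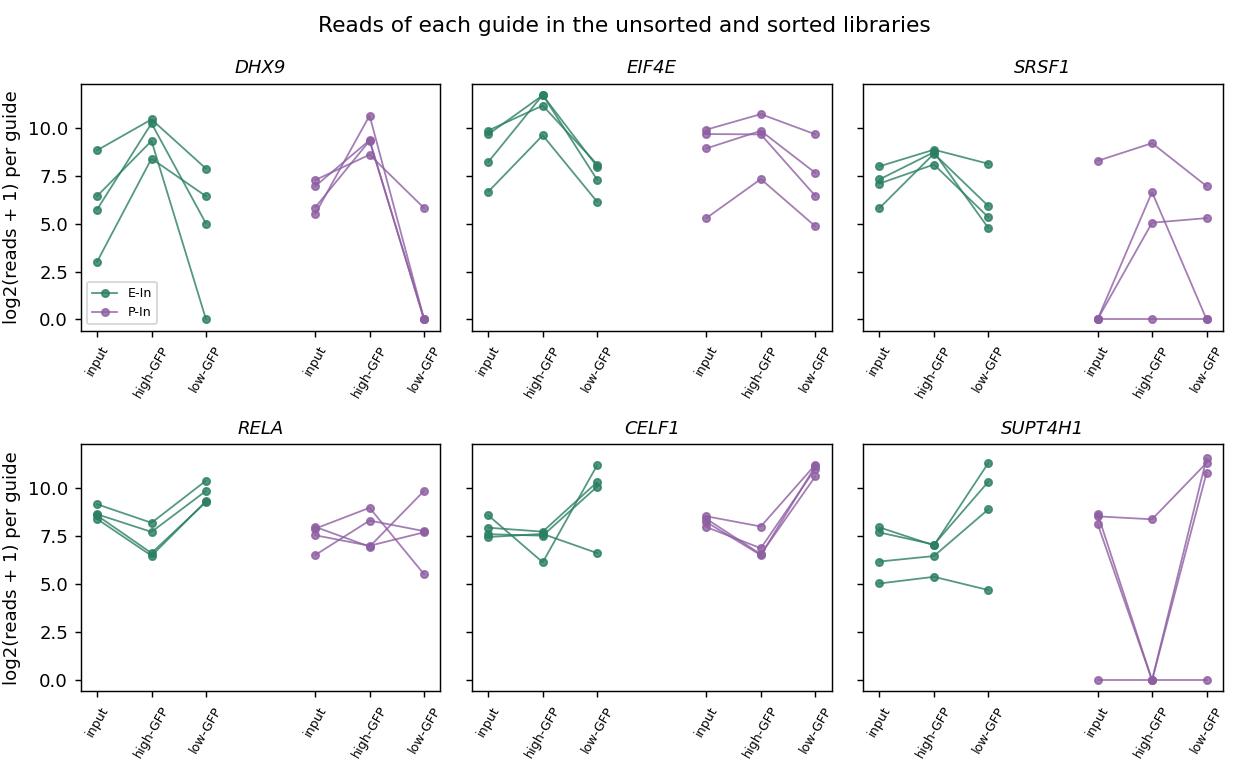
Reads of each guide on a log2 axis (reads plus 1) for 6 genes in the input, high-GFP and low-GFP libraries of E-In (green) and P-In (purple), with 1 line per guide. DHX9 guides are higher in high-GFP for both reporters, and 3 of the 4 SRSF1 guides start at 0 reads in the P-In input.

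The 4 guides given here each matched 1 site in the hg38 genome, in a coding exon of the gene. The DHX9 guide TCAATCACAGCATCCAAAGG lies on chromosome 1 from 182879371 to 182879390 and had 1588 reads in P-In high-GFP and 0 in low-GFP, and 1201 and 31 in E-In. The SUPT4H1 guide AGGACAGCTGGGTCTCCAAG lies on chromosome 17 from 58347542 to 58347561 and had 0 and 3046 reads in P-In, and 130 and 2595 in E-In. The SRSF1 guide CGGGTCCTCGAACTCAACGA lies on chromosome 17 from 58006946 to 58006965 and had 422 reads in E-In high-GFP and 26 in low-GFP, but 32 and 38 in P-In. The RELA guide GCTTCCGCTACAAGTGCGAG lies on chromosome 11 from 65662006 to 65662025 and had 89 reads in E-In high-GFP and 643 in low-GFP.

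Against the unsorted input, 7 genes passed in the 4 comparisons of a sorted pool. In the P-In low-GFP pool PA2G4 (3.14 ± 1.55), the centromere protein gene CENPI (4.59 ± 2.54), the exosome helicase gene SKIV2L2 (4.11 ± 1.17) and CELF1 were higher than in the input. The P-In input held 0 reads for 3 of the 4 SKIV2L2 guides and 2 of the 4 CENPI guides, so these 2 ratios depend on the pseudocount, and the CENPI guide with the most input reads went from 647 to 479. In the E-In low-GFP pool ZFC3H1 (-3.04 ± 0.57), LUC7L3 (-2.07 ± 0.51) and WASH1 (-2.72 ± 0.80) were lower than in the input. Each WASH1 guide matched at least 3 sites in the genome. The high-GFP pools passed 0 genes against the input in both reporters by rank aggregation, where 1056 genes in P-In and 1100 in E-In had an unadjusted permutation p under 0.05 for enrichment, of 19073 and 19095 tested, and chance gives 5%. DHX9 was among the 3 smallest p-values in E-In high-GFP against input, at 3.31 ± 1.5 (permutation p = 1.8e-05, false discovery rate 0.158). VARS and KARS, which charge transfer RNAs, led P-In high-GFP against input at 4.16 ± 2.06 and 2.05 ± 0.15.

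The leading genes of the reporters, which share no library, overlapped. Among the top 1% of genes (190 of 19011), 13 were shared toward high-GFP against 1.90 expected (hypergeometric exact p = 6.2e-08), with DHX9, DNA2, PPP1R8, VARS and RPLP1 among them. Toward low-GFP 23 were shared (exact p = 1.5e-18), including SUPT4H1, SUPT5H, SUPT6H, LEO1, CELF1, PA2G4, PCBP2, MORC2 and SRP14. The shared genes also held OR4F29, an olfactory receptor gene, and USP17L27, whose guides matched several sites each, and HIST2H3D, for which 3 of 4 guides did. Fisher's method across both reporters passed 95 genes toward high-GFP, led by DHX9, and 36 toward low-GFP, led by SUPT4H1 (-8.57 in P-In and -2.89 in E-In). OR4F29, from the olfactory receptor list, was among the 3 smallest combined p-values toward high-GFP (false discovery rate 0.00114). Its median log2 ratios were 5.19 in P-In and 1.998 in E-In. USP17L27 and HIST2H3D also passed, so passing Fisher's method is not by itself evidence that a gene acts on fluorescence. A gene can pass Fisher's method through 1 reporter, as did TAF6 (-4.29 in P-In and 2.34 in E-In) and S100A5 (5.03 and -0.44). With the squared larger p-value, which needs both reporters, 21 genes passed toward high-GFP and 24 toward low-GFP.

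Of the E-In genes past the threshold that were tested in P-In, 45 of 50 higher in high-GFP and 18 of 22 higher in low-GFP moved the same way in P-In. Together 87.5% moved the same way, against 52.9% of other genes (one-sided Fisher exact p = 4.6e-10). That p counts genes as independent and holds no error between sorts, and the other genes were not matched on read number. Across all genes, which are not independent replicates, Pearson's r between the reporters' log2 ratios was 0.15 and Spearman's rho was 0.10.

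**Figure D3:**
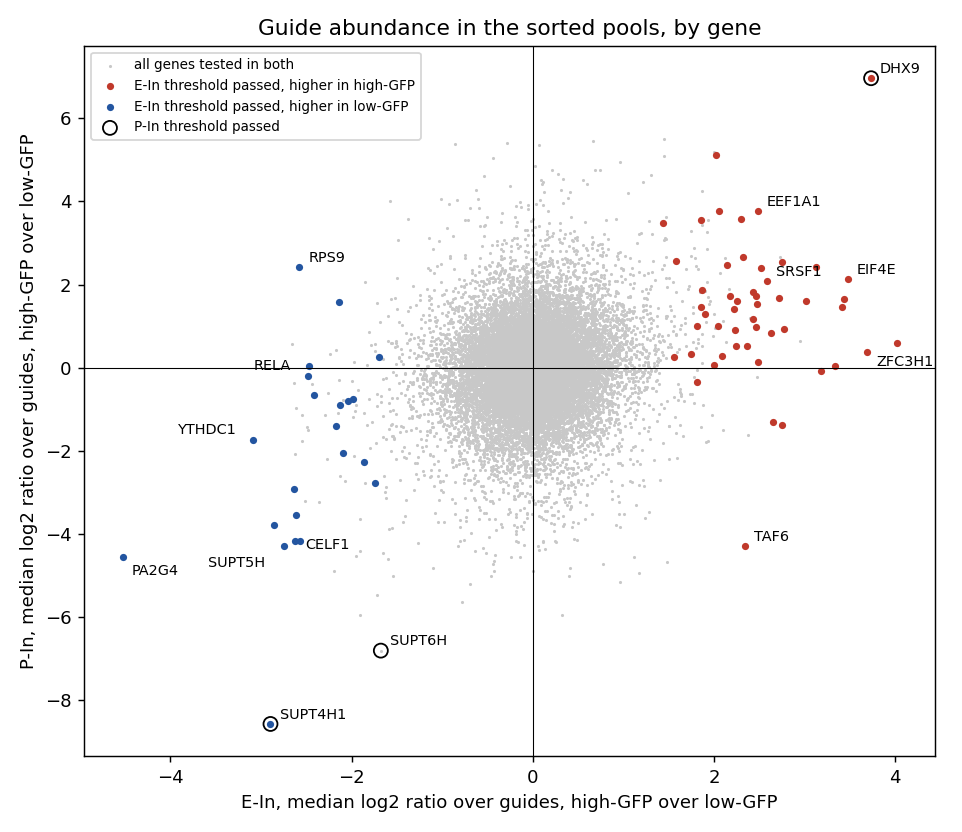
Median log2 ratio over guides, high-GFP over low-GFP, in E-In (x axis) and P-In (y axis) for each gene tested in both, with genes past the threshold in E-In coloured and those past it in P-In circled. DHX9 lies at 3.73 and 6.96 and SUPT4H1 at -2.89 and -8.57, and ratios of guides absent from a pool depend on the pseudocount.

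When both reporters were fitted together in edgeR, with the reporter as a term and 2 residual degrees of freedom, 130 genes passed for high-GFP against low-GFP, 56 higher in high-GFP and 74 higher in low-GFP. DESeq2 on the same sums passed 100 higher in high-GFP and 94 higher in low-GFP. SUPT4H1 (log2 fold change -4.02, adjusted p = 3.1e-13), CELF1 (-3.46, adjusted p = 9.4e-13) and PA2G4 (-3.71, adjusted p = 3.5e-12) led toward low-GFP in edgeR, with lower sums in high-GFP for both reporters. DHX9 led toward high-GFP at 4.45 (adjusted p = 1.6e-09 in edgeR), followed by EIF4E at 2.66 (adjusted p = 1.7e-08). SUPT6H passed in edgeR at -4.16 (adjusted p = 0.00067) and did not pass in DESeq2 (adjusted p = 0.613). SRSF1 had 1.99 and RELA -1.31 without passing in edgeR (adjusted p = 0.113 and 0.136), and in DESeq2 SRSF1 passed (adjusted p = 0.0131) and RELA did not (0.198). For high-GFP against input 3 genes passed and for low-GFP against input 12. The fit treats the reporters as repeats of one another. A guide-level test in edgeR with fry passed 0 genes in each comparison. In it 1078, 769 and 699 of 19098 genes had an unadjusted p under 0.05, and chance gives 5%. With 2 residual degrees of freedom fry had little power over so many genes. Even DHX9 had a fry p of 0.0136 (false discovery rate 0.803) for high-GFP against low-GFP. The 0 is therefore no evidence that these genes lack an effect.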

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

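The test of the spread of non-targeting guides and that of more control guides in the starting library were chosen only after the result was seen. Genes past the threshold in 1 reporter had a median log2 ratio of the opposite sign in the other in 13 cases, each from 1 library per group, and the differences were not tested. For high-GFP against low-GFP, TAF6 had 2.34 in E-In and -4.29 in P-In, RPS9 -2.57 and 2.41, TNFRSF1A -2.14 and 1.57, LENG8 2.75 and -1.39, ELP3 2.65 and -1.31, SIK2 1.81 and -0.34, FAU -1.70 and 0.25, LUC7L3 3.19 and -0.089, and NF2 -2.47 and 0.043. The P-In sign of LUC7L3 turned when libraries were scaled by total reads (0.039) or on non-targeting guides (0.053) and in the ratio of summed counts (0.37), and that of NF2 in the last (-0.055). For low-GFP against input, SKIV2L2 had 4.11 in P-In and -2.14 in E-In, and CENPI 4.59 and -0.55, with 3 and 2 of their 4 guides at 0 reads in the P-In input. In the same comparison WASH1 had -2.72 in E-In and 0.73 in P-In, and ZFC3H1 -3.04 and 0.54. LENG8, ELP3 and SIK2 were named after their values were seen.

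More genes passed in E-In (75) than in P-In (3) for high-GFP against low-GFP. Fewer reads in P-In are argued against: E-In reads thinned to the P-In totals passed a median of 75.5 genes over 20 draws (63 to 86). That the E-In genes lack any effect on fluorescence in the P-In sort is argued against by the 87.5% of them that moved the same way there. Whether they act on the reporter itself cannot be told from this share. The DNA replication list (0.68 in E-In and 0.79 in P-In) and the proteasome list (0.60 and 0.82) also lay toward high-GFP in both. Fewer cells per guide in the P-In sorts may account for the difference: the log2 ratios of non-targeting guides spread 2.38 times as widely in P-In (SD 1.19) as in E-In (0.50), and at least 17.9 times as many well-covered guides were lost. A biological difference between the reporters stays open.

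Guides of the E-In genes past the threshold, which include SRSF1 and SRRT, had a median of 216.5 input reads against 333 for all targeting guides. Guides with few reads vary more and could fill both ends of the ranking. When guides were ranked within 20 bins of mean reads, 52 of the 75 genes (69.3%) still passed, which argues against this as the whole cause. It stays open for the others, SRSF1 among them. No biological explanation was tested.

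Non-targeting guides had 2.29 to 2.56 times the median reads of olfactory receptor guides in the 6 libraries. Slower growth of cut cells could not be told apart from more copies of these guides in the starting library. Olfactory receptor guides with 2 or more sites (137 guides) had 0.927 times the input reads of single-site ones in P-In and 0.986 times in E-In, between the bounds set in advance. The lowest ratio, 2.29, fits either, since a count of the starting library was not analysed here. No biological difference between groups bears on this.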

How the results depend on the processing

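The ranks within bins of mean reads and the single-site guides were chosen after seeing the data; the other alternatives were fixed before the data were examined. For high-GFP against low-GFP, the count in E-In was 75 and went to 148 without the most extreme guide of each gene (73 of the 75 kept), to 309 at a threshold of 0.25 and to 140 with ranks within bins (52 kept). In P-In it was 3 and went to 13 at 0.25 and to 6 within bins. Against input, a threshold of 0.25 gave 3 genes for P-In high-GFP, 17 for P-In low-GFP, 21 for E-In high-GFP and 38 for E-In low-GFP, and ranks within bins gave 1, 2, 9 and 18. A pseudocount of 20 gave 1 gene for P-In high-GFP against input, and single-site guides gave 2 for P-In low-GFP. The looser threshold explains its own counts; for the others the cause was not tested. In the remaining settings each count stayed within 1.5 times its main value.

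The overlap of the top 5% was 124 toward high-GFP (47.6 expected) and 114 toward low-GFP, larger by construction. The combined test passed 21 genes toward high-GFP with the squared larger p-value, which needs both reporters, and 59 toward low-GFP with ranks within bins; the cause of the latter was not tested. For high-GFP against low-GFP, edgeR without TMM passed 152 genes and DESeq2 194 (100 higher in high-GFP, 94 higher in low-GFP), against 130. In edgeR, fry on guides passed 0 genes in each of the 3 comparisons, where 2 residual degrees of freedom left it little power. For high-GFP against input, edgeR without TMM passed 6 genes and DESeq2 passed 7; the cause was not tested. The edgeR filter removed no gene, and all guide sequences were distinct, so these alternatives moved nothing and the second was not run.

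For high-GFP against low-GFP, no named gene past the threshold changed direction under any setting run. Direction is the sign of the median log2 ratio. The settings on ranks, bins, score, extreme guide and threshold leave that ratio as it was and could not turn it. Only those on scaling, pseudocount, read filter, single-site guides and averaging could. Ranks within bins ended the call for 10 of the named results and single-site guides for 4. Settings fixed in advance also ended calls, all in E-In. A pseudocount of 1 ended 5 (CDK13, DHX15, PSMA5, SRSF7 and VARS), and all ranks ended 6, the same genes and PSMA6. A pseudocount of 20 ended 3 (DNA2, PCNA and PSMA6) and the filter on input reads 3 (CDK9, DHX15 and PSMA5). Scaling on non-targeting guides moved the median of all genes to 0.15 in E-In and 0.11 in P-In, and 23 of 52 list medians moved by more than the SD of random lists. The P-In libraries limit what can be seen, as 6.99% and 5.77% of guides were absent from their sorted pools.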

Other observations

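The tests on ribosomal subunits and the choice of NF-kB genes were made after the result was seen. Cytosolic ribosome genes parted by subunit in E-In. The 32 genes of the small subunit had a median log2 ratio of -1.38 in high-GFP over low-GFP (quartiles -1.74 to -0.83) and 2 of them lay above 0, while the 46 genes of the large subunit had 0.45 (quartiles 0.005 to 1.05) and 35 lay above 0. RPS9, RPS6 and FAU, which encode small subunit proteins, passed toward low-GFP over all genes, and RPLP2, of the large subunit stalk, toward high-GFP, though not with ranks within bins of mean reads. GNB2L1, which encodes the small subunit protein RACK1, also passed toward low-GFP at -2.86.

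The subunit medians differed by -1.82 in E-In, the observation that prompted the split, so no p is given for it. Whether slower growth alone is the cause was not decided, since its test used this same difference. The medians lay on opposite sides of 0, with quartiles that did not overlap. Both sets of guides were scarce in the E-In input against 358.5 reads for olfactory receptors. They were not equally scarce, at 195 reads for the small and 137 for the large subunit. In P-In the subunit medians differed by -0.92, in the same direction (permutation p = 0.016, with 30 and 44 genes). That p shuffled genes within 1 pair of libraries and holds no error between sorts. Above 0 in P-In lay 11 of the 30 small subunit genes and 29 of the 44 large subunit genes. RPS9 (2.41) and FAU (0.25) had the opposite sign in P-In, while RPS6 (-2.27), GNB2L1 (-3.79) and RPLP2 (1.00) kept theirs. A candidate explanation is that loss of the small and of the large subunit acts differently on the GFP signal, for example on its translation, which was not measured.

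RELA and TNFRSF1A guides were higher in the E-In low-GFP pool, and may point to a dependence of the E-In signal on NF-kB. The other 19 NF-kB activators had a median log2 ratio of -0.15, at the 9.56th percentile of random lists, between the bounds set in advance, so this test did not decide; TRADD, CHUK and IKBKG passed toward low-GFP when adjusted over the list alone. The 7 NF-kB inhibitors had a median of 0.85, at the 100th percentile, with NFKBIA, CYLD and TNIP1 past the threshold when adjusted over the list alone, which goes with a signal that inhibitors hold down. In P-In the median log2 ratio was -0.195 for RELA (one-sided permutation p = 0.377) and 1.57 for TNFRSF1A. The inhibitors had -0.63 there, at the 7.22nd percentile, and the activators -0.41, at the 5.66th. The difference between the reporters was not tested.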
